A study of Mus musculus with 3 samples.

How the data were processed

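Gene expression was measured on 3 Illumina MouseRef-8 v2.0 expression beadchip arrays, which carry bead-bound probes read in 1 colour after biotin labelling of total RNA. Per the labels' protocols, Rag1-null mice, which lack mature T and B cells, received an injection of adenovirus in the part of the pancreas next to the spleen, and cells carrying the red fluorescent protein Cherry were later sorted from the digested acinar fraction, after removal of the islets, by fluorescence-activated cell sorting. All 3 samples carry a title that calls them induced delta cells and differ only in the replicate number, 1 to 3. The series title gives day 10 without saying from which event days were counted. The extraction protocol and the series' design text speak of induced beta cells instead, so the labels disagree on the name of the cells. The group was taken from the titles. No untreated, control or other endocrine sample was analysed here, so no comparison between groups was made.

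The first deposited table holds an average bead intensity per probe on a linear scale and a detection p-value per probe, per the file headers. The lowest value of the authors' intensities was 41.8, 38.7 and 36.0 on the arrays of replicates 1, 2 and 3, so no background close to the negative controls' median (60.4, 54.2 and 51.9, as implied by the detection p-values) had been subtracted. The table is named non-normalized, yet the 3 deposited intensity columns have the same mean over all probes, 211.8, while their medians differ (65.9, 59.5 and 57.2). The arrays had therefore been scaled to a common mean before deposit. The deposited detection p-values move in steps that imply 798 negative controls per array. The second deposited table holds the authors' processed intensity values. Its columns share 1 distribution, with medians of 53.5, 53.5 and 53.6 and a common minimum of 33.6, and each ranks the probes exactly as the scanner column of the same array does (Spearman's rho = 1). It is therefore linear, quantile normalized and not centred. Its common distribution is not the mean of the 3 scanner columns, so the target of that normalization is unknown. Aligner and genome build do not apply; the scanner software and its version are not given in the sources used here.

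The arrays held 25697 probes. A platform annotation gave 1 gene symbol for 23978 of them and several symbols for 0; 1719 probes were unnamed here. Symbols were checked through the Entrez identifier against a RefSeq gene table of the assembly GRCm38.p6, used for names alone, where 23962 probes matched, 0 symbols changed and 16 kept the annotation's symbol. This left 16593 genes, of which 4777 had more than 1 probe. No probe sequence was used, so it is not known which part of a transcript a probe covers, nor which probes bind near-identical family members such as the digestive proteases, the Reg proteins or the kallikreins. Values of such genes are uncertain.

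A probe was called detected where its detection p was under 0.05 on all 3 arrays, and a gene where any of its probes was. For levels, intensities were background-corrected by normexp with the negative-control mean and variance inferred from the detection p-values, with an offset of 16, then quantile normalized and taken to log2 (neqc in limma 3.58.1, R 4.3.3). On this scale the 95th percentile of the negative controls lay at 4.83, 4.77 and 4.75 on the arrays of replicates 1, 2 and 3. A gene's level is that of its brightest probe. Levels are given as mean ± SD over the 3 arrays (n = 3). Probes differ in their efficiency, so levels of different genes were not set against each other. The arrays' number limits the precision: an SD from 3 arrays is itself imprecise. Nothing in the labels says whether the 3 samples came from separate animals, so the spread between these samples may be technical. The F test below uses that spread, and Fisher's exact test does not.

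The tests of the report, the 23 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Exceptions were 3 alternatives (a robust prior variance, lists without members held by another list, and a background without olfactory receptors) and the closing tests, of which those on gut hormones and gene families were set before any gene's values were seen and those on probe pairs, myeloid genes and acinar enzymes later. The lists held 242 genes, of which 206 had a named probe and 36 did not, among them Ins1, Fev, Pcsk2, Cpe and Pnlip. For each list, Fisher's exact test (two-sided) compared detected and undetected genes in the list and among all other genes, with Benjamini-Hochberg adjustment over the 23 lists. Genes are not independent replicates, so these p-values describe the arrays' gene content. For each of the 17 lists with at least 3 detected members, the median deviation of the members from their 3-array means was taken on each array. The range of these 3 medians was placed among 10000 random lists of the same size matched on level in 10 bins. For single probes, an F test in limma compared the variance between the 3 arrays with the variance expected at that level (fitFDist with a trend, upper side, Benjamini-Hochberg). Genes named in the text are all members of the hormone, delta cell and endocrine transcription factor lists, the first 4 measured members of every other list, and the 5 named probes with the smallest p in the F test, for which the tested probe is shown in place of the brightest. Others are marked as chosen after their values were seen.

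The procedures were tested on simulated data. Of 20 random lists of 10 genes, 0 were called by the Fisher test, and of 20 lists with 9 of 10 genes detected, 20 were called. The latter 20 lists had the same counts and so the same p-value. They show nothing about the power for lists with a smaller share detected. Of 10 lists raised by 0.3 log2 units on 1 array, 10 exceeded the 95th percentile, as did 1 of 10 unchanged lists. That shift is large against the 95th percentile of random lists, 0.123 for the 10 detected endocrine transcription factors. Smaller shifts and shorter lists were not tried. The F test was tried on 8486 simulated probes, with 50 probes each whose SD was raised by a factor of 5, 10, 20 or 40. It called 0, 2, 16 and 38 of these, and 0 of the 8286 unchanged probes. The expected variance was refitted with all raised probes included, which could hide some of them. The power for a single such probe in the data was therefore not measured, and these counts may understate it. Alternatives covered the detection threshold, the number of arrays required, the choice of probe, a one-sample limma test against background, the gene background, other normalizations including the authors' processed values, and each replicate left out.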

Results

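The data comprised 3 replicate arrays of sorted cells from the acinar fraction of the mouse pancreas, taken at day 10. An adenovirus had been injected into the gland, and the sample titles call the sorted cells induced delta cells. Delta cells are the somatostatin-secreting cells of the islet. The question taken from the titles was which genes such cells express. The extraction protocol and the design text call them induced beta cells instead, and no array of native delta or beta cells was analysed here. In the published work on these cells, as far as it is known here, the virus carried Neurog3, the transcription factor that starts endocrine development; the labels name the virus but not its gene. The 3 arrays detected 9145, 9592 and 9713 of the 25697 probes (35.6%, 37.3% and 37.8%), and 8486 probes were detected on all 3. The 99th percentile of the signals was 37.8, 45.2 and 47.7 times the median negative control on the arrays of replicates 1, 2 and 3. By gene, 6787 of 16593 (40.9%) were detected on all 3 arrays. Genes of the olfactory receptor family, which few tissues outside the nose use, were detected for 19 of 1058 (1.80%). In the other direction, of the genes with more than 1 probe and at least 1 probe detected, 80.3% also had a probe that was not, so a probe at background does not show that its gene was silent.

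Transcripts of the islet hormones were detected broadly in the RNA of the sorted cells. Each array reads many cells together, and no islet, unsorted or untreated sample was analysed. Which cells held which hormone transcript is therefore not shown. The probe for Sst, which encodes somatostatin, the delta cell hormone, read 13.81 ± 0.046 on the log2 scale (mean ± SD, n = 3 arrays here and below), against a background limit of 4.75 to 4.83. Probes for 7 other hormone genes were also detected on all 3 arrays. Pyy, which encodes peptide YY, read 12.71 ± 0.018, Ins2, one of the insulin genes of the mouse, 11.38 ± 0.039, and Gcg, which encodes glucagon, 9.21 ± 0.079. Ghrl, which encodes ghrelin, read 9.18 ± 0.066, Cck, which encodes cholecystokinin, 7.0 ± 0.027, Iapp, which encodes islet amyloid polypeptide, 6.13 ± 0.34, and Ppy, which encodes pancreatic polypeptide, 6.08 ± 0.042. Gast, which encodes gastrin, was not above background on any array (4.36 ± 0.056), and Ins1 had no named probe. In all, 8 of 9 measured hormone genes were detected (88.9%, against 40.9% of other genes; odds ratio 11.6, 95% interval 1.55 to 512; Fisher's exact test, adjusted p = 0.0343). The call was lost when 2 of 3 arrays sufficed for detection (adjusted p = 0.0743), when olfactory receptors were left out of the background (adjusted p = 0.0956) and when the 4 hormones that other lists also hold were removed (4 of 5 detected, adjusted p = 0.398; the last 2 were chosen after seeing the data; Fisher's exact test throughout).

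**Figure D1:**
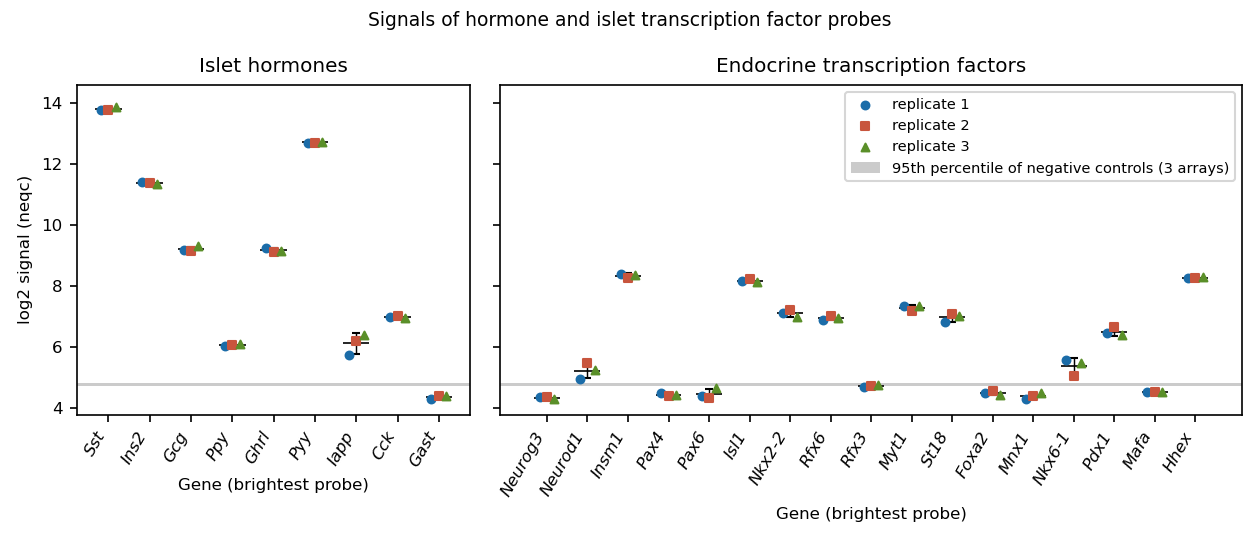
Log2 signals (vertical axis, neqc scale) of the brightest probe of each measured hormone gene (left) and endocrine transcription factor (right); symbols are the 3 replicate arrays, the horizontal tick and bar are mean ± SD (n = 3), and the grey band spans the 95th percentile of the negative controls on the 3 arrays, 4.75 to 4.83. Sst, Pyy, Ins2, Gcg and Ghrl lie above the band on every array and Gast, Neurog3, Pax4, Pax6, Foxa2, Mnx1 and Mafa lie in or below it; heights of different genes are not comparable.

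Of the delta cell list, 5 of 7 genes were detected, which did not pass the test (Fisher's exact test, adjusted p = 0.306). Besides Sst these were Hhex, the homeobox factor that delta cells require (8.28 ± 0.016), Ffar4, a fatty acid receptor of delta cells (8.26 ± 0.018), Rbp4, which encodes a retinol carrier (6.39 ± 0.28), and Pdx1, a homeobox factor shared by beta and delta cells (6.52 ± 0.13). The ghrelin receptor gene Ghsr (4.58 ± 0.13, 3 probes) and Crhr2, a receptor for urocortins (4.50 ± 0.035), were not above background on any array.

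Transcription factors of endocrine development were detected for 10 of 17 measured genes (58.8%; Fisher's exact test, adjusted p = 0.306). Insm1 (8.34 ± 0.079), Isl1 (8.19 ± 0.065), Myt1 (7.30 ± 0.084), Nkx2-2 (7.11 ± 0.12), St18 (6.99 ± 0.15) and Rfx6 (6.96 ± 0.066) were detected on all 3 arrays, as were Hhex and Pdx1, with values given above. Nkx6-1 (5.39 ± 0.27) and Neurod1 (5.24 ± 0.26) were also detected on all 3 arrays, within 1 log2 unit of the background limit. The Neurog3 probe was at background on every array (4.34 ± 0.042). Whether that probe lies in the part of the gene that a virus would express is not given in the sources used here, so it does not check the induction. Pax4 (4.45 ± 0.055), Pax6 (4.47 ± 0.17), Mnx1 (4.40 ± 0.094), Foxa2 (4.50 ± 0.053) and the beta cell factor Mafa (4.53 ± 0.010) were not above background on any array, and Rfx3 was on 1 (4.73 ± 0.036). Fev had no named probe.

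Granule and secretory genes of neuroendocrine cells were detected for 10 of 15 measured members (66.7%; Fisher's exact test, adjusted p = 0.203). Chga, which encodes chromogranin A, read 9.78 ± 0.20 and Chgb, which encodes chromogranin B, 8.06 ± 0.19. Scg3, which encodes secretogranin III, read 5.46 ± 0.30, and Scg2 was not above background (4.37 ± 0.071). Of the beta cell list 5 of 11 genes were detected (45.5%; Fisher's exact test, adjusted p = 0.929). These were Ins2, Iapp, Pdx1, Nkx6-1 and, named after its value was seen, Ero1b (5.6 ± 0.17), an oxidoreductase of the endoplasmic reticulum. Of the alpha cell list 3 of 5 were detected (60%; Fisher's exact test, adjusted p = 0.548). These were Gcg, Ttr, which encodes transthyretin (11.09 ± 0.10), and Irx2, an Iroquois homeobox factor (5.52 ± 0.12), while Irx1 was at background (4.37 ± 0.031).

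Transcripts of the acinar cell, the digestive enzyme-secreting cell of the exocrine pancreas, were detected without exception among the measured enzyme genes. All 17 acinar enzyme and secretory genes were detected on all 3 arrays (100%, against 40.8% of other genes; odds ratio of at least 5.97 by its 95% interval; Fisher's exact test, adjusted p = 5.71e-06). Cpa1, a carboxypeptidase, read 14.50 ± 0.019, Cela1, an elastase, 14.44 ± 0.039, Ctrb1, a chymotrypsinogen, 14.59 ± 0.0068, and Prss2, a trypsinogen, 14.22 ± 0.089. Of the acinar transcription factors, 6 of 7 were detected (85.7%), which did not pass the test (Fisher's exact test, adjusted p = 0.0978). It passed at a detection p of 0.01 (adjusted p = 0.0440), with 2 of 3 arrays (adjusted p = 0.0274) and without replicate 1 (7 of 7 detected, adjusted p = 0.0213; Fisher's exact test throughout). Gata4, named after its value was seen, was above background on 2 arrays (4.71 ± 0.23). Ptf1a, the factor that specifies acinar cells, read 8.84 ± 0.033, Bhlha15, also known as Mist1, 9.27 ± 0.0041, Rbpjl, a partner of Ptf1a, 12.25 ± 0.041, and Nr5a2, a nuclear receptor of acinar cells, 7.18 ± 0.20.

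**Figure D2:**
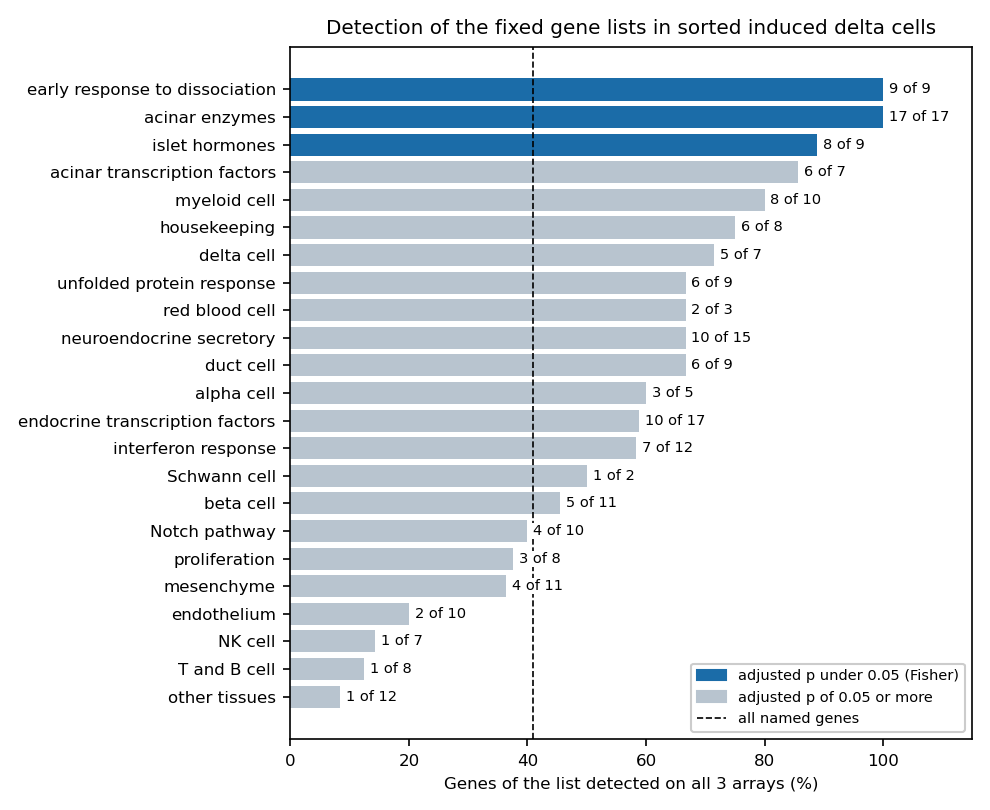
Percent of measured genes detected on all 3 arrays (horizontal axis) for each of the 23 fixed gene lists (vertical axis), with the number detected of those measured beside each bar; dark bars passed Fisher's exact test after adjustment and the dashed line is the share of all named genes, 40.9%. The 3 dark bars are the early response, acinar enzyme and islet hormone lists, at 9 of 9, 17 of 17 and 8 of 9.

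Genes of other cell types that the pancreas or the sort could hold were detected unevenly, and none of the duct, myeloid, mesenchyme and endothelial lists passed the test. Of the duct cell list 6 of 9 were detected (Fisher's exact test, adjusted p = 0.306): Krt7, a keratin of duct cells (7.98 ± 0.099), and Sox9, a progenitor and duct factor (5.73 ± 0.11), were above background, and Krt19 (4.55 ± 0.13) and Car2 (4.35 ± 0.036) were not. Of the myeloid list 8 of 10 were detected (80.0%; Fisher's exact test, adjusted p = 0.0978), among them Adgre1, which encodes the macrophage marker F4/80 (8.84 ± 0.19), and Lyz2, which encodes lysozyme (10.13 ± 0.30), while Ptprc, the general leukocyte marker CD45 (4.40 ± 0.044), and Itgam (4.34 ± 0.019) were at background. The myeloid call passed with a stricter detection threshold of 0.01 (adjusted p = 0.0299) and with detection p-values adjusted within each array (adjusted p = 0.0393; Fisher's exact test in both). Of the mesenchyme list 4 of 11 were detected (Fisher's exact test, adjusted p = 1), with Col3a1 at 5.54 ± 0.042, Col1a2 at 4.85 ± 0.066, and Col1a1 (4.46 ± 0.083) and Vim (4.39 ± 0.036) at background. Of the endothelial list 2 of 10 were detected (Fisher's exact test, adjusted p = 0.353). These were Plvap (6.44 ± 0.090) and Esam (7.20 ± 0.065), named after their values were seen. Pecam1, Cdh5 and Kdr were at background on all arrays (4.56 ± 0.064, 4.24 ± 0.011 and 4.66 ± 0.017), and Emcn was above it on 2 (4.79 ± 0.23).

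Lymphoid genes were mostly at background in these samples from Rag1-null mice. Of the T and B cell list 1 of 8 was detected, Cd3e, a subunit of the T cell receptor complex (6.89 ± 0.24), with Cd3g (4.31 ± 0.011), Cd3d (4.28 ± 0.0082) and Cd4 (4.46 ± 0.039) at background (Fisher's exact test, adjusted p = 0.306). Of the natural killer list 1 of 7 was detected, Prf1, which encodes perforin (9.62 ± 0.14), named after its value was seen, with Nkg7 (4.38 ± 0.042), Klrb1c (4.50 ± 0.096), Ncr1 (4.33 ± 0.017) and Gzma (4.27 ± 0.044) at background (Fisher's exact test, adjusted p = 0.363). Of 3 measured red blood cell genes, Hba-a1 (6.09 ± 0.072) and Slc4a1 (5.28 ± 0.14) were detected and Alas2 was not (4.45 ± 0.057; Fisher's exact test, adjusted p = 0.730). Of 2 measured Schwann cell genes, Mbp was detected (7.83 ± 0.061) and S100b was not (4.30 ± 0.043; Fisher's exact test, adjusted p = 1). Of 12 genes of unrelated tissues 1 was detected, the kidney gene Umod (5.66 ± 0.052), named after its value was seen (Fisher's exact test, adjusted p = 0.133), while Prm1 (4.50 ± 0.10), Tnp1 (4.42 ± 0.084), Tnp2 (4.43 ± 0.054) and Gfap (4.41 ± 0.065) were at background. Of 8 housekeeping genes 6 were detected (Fisher's exact test, adjusted p = 0.203), including Actb (13.01 ± 0.051), Gapdh (10.47 ± 0.29), Hprt (7.68 ± 0.093) and Tbp (5.52 ± 0.026). The 2 that were not, Eef1a1 (4.37 ± 0.063) and Pgk1 (4.35 ± 0.022), named after their values were seen, encode proteins that every cell uses.

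Early-response genes that cell dissociation is known to induce were detected for all 9 measured members (100%, against 40.9% of other genes; odds ratio of at least 2.85 by its 95% interval; Fisher's exact test, adjusted p = 0.00367). Fos read 12.00 ± 0.070, Jun 8.36 ± 0.12, Junb 11.21 ± 0.081 and Egr1 13.53 ± 0.070; these are transcription factors switched on within minutes of a stimulus. Of the unfolded protein response list 6 of 9 were detected (Fisher's exact test, adjusted p = 0.306), with Herpud1, a protein of endoplasmic reticulum-associated degradation, at 12.86 ± 0.059 and Ddit3, which encodes CHOP, at 6.76 ± 0.096. Hspa5, which encodes the chaperone BiP, was detected on 2 arrays (5.17 ± 0.33), and Atf4 on none (4.31 ± 0.065). Of the interferon response list 7 of 12 were detected (Fisher's exact test, adjusted p = 0.363), with Ifit3 at 9.45 ± 0.036, Irf7 at 6.31 ± 0.19, Isg15 at 5.35 ± 0.085, and Ifit1 at background (4.24 ± 0.047). Of the Notch pathway list 4 of 10 were detected (Fisher's exact test, adjusted p = 1), with the receptor gene Notch1 at 7.82 ± 0.18 and the target gene Hes1 at 6.55 ± 0.083; Notch2 was at background (4.58 ± 0.12), and Jag1 was above it on 1 array (4.68 ± 0.17). Of 8 proliferation genes 3 were detected (Fisher's exact test, adjusted p = 1): Aurka, a mitotic kinase, read 5.47 ± 0.20, and Top2a (4.27 ± 0.079), Cdk1 (4.44 ± 0.031) and Ccna2 (4.26 ± 0.019) were at background. With no control sample, none of these shares shows a change.

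The 5 named probes with the smallest p in the F test, none of them of a list gene, were those of Reg3b (range between arrays 0.80 log2 units), Scnm1 (1.35), Atp5a1 (0.87), Reg3g (0.57) and Klk1b5 (0.68). Reg3b and Reg3g encode secreted lectins of the inflamed pancreas and gut, and Atp5a1 a subunit of the mitochondrial ATP synthase. These probes of Reg3b, Atp5a1, Reg3g and Klk1b5 were highest on the array of replicate 3 and that of Scnm1 on replicate 1. For 3 of these genes a brighter probe ranged less between the arrays. The brighter probe of Klk1b5 was highest on replicate 2 (range 0.026), and on replicate 3 with median scaling (0.15). That of Scnm1 was highest on replicate 3 (0.20; 0.36 with median scaling). That of Reg3b was also highest on replicate 3, with a range of 0.16 (0.095 with median scaling). Whether differences of probes as bright as those of Reg3b and Klk1b5 are compressed was not tested. Across the 8486 probes detected on all arrays, Pearson's r of log2 levels was 0.995 for replicates 1 and 2, 0.995 for replicates 1 and 3, and 0.996 for replicates 2 and 3; these are correlations across probes, which are not independent replicates. The median absolute difference per pair was 0.104, 0.102 and 0.0916 log2 units, and 2, 1 and 1 probes differed by more than a factor of 2. The median SD per probe was 0.0872, and 90% of probes had an SD under 0.191. No probe passed the F test in limma after adjustment over all 8486 probes (smallest adjusted p = 0.307; 407 probes had an unadjusted p under 0.05), while 36 passed with median scaling and 22 when all probes were tested. Adjusted over the list alone, 4 genes passed: Lyz2 and H2-Aa, an MHC class II gene named after its value was seen, in the myeloid list (limma F test, adjusted p = 0.00249 for both), Gapdh in the housekeeping list (0.00376) and Cd3e, the 1 tested gene of its list (0.0288). Without a variance trend, Lyz2 and H2-Aa (0.1002 for both) and Gapdh (0.160) did not pass and Cd3e did (0.0476). With median scaling, Gapdh (0.0980) and Cd3e (0.187) did not, nor did Cd3e when all probes were tested (0.0968). Without replicate 3, Lyz2 (0.585) and H2-Aa (0.675) no longer passed. Without replicate 2, Gapdh (0.354) and Cd3e (0.269) did not, and without replicate 1, Cd3e (0.157) did not. Prf1, also the 1 tested gene of its list, passed without replicate 1 (0.0426) and without replicate 3 (0.0437). Hes6, a Notch list gene named after its value was seen, passed without replicate 3 (0.0476). All these values are from the limma F test, adjusted over the list alone. For a list with 1 tested gene that is the unadjusted p, and no correction was made across the lists.

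**Figure D3:**
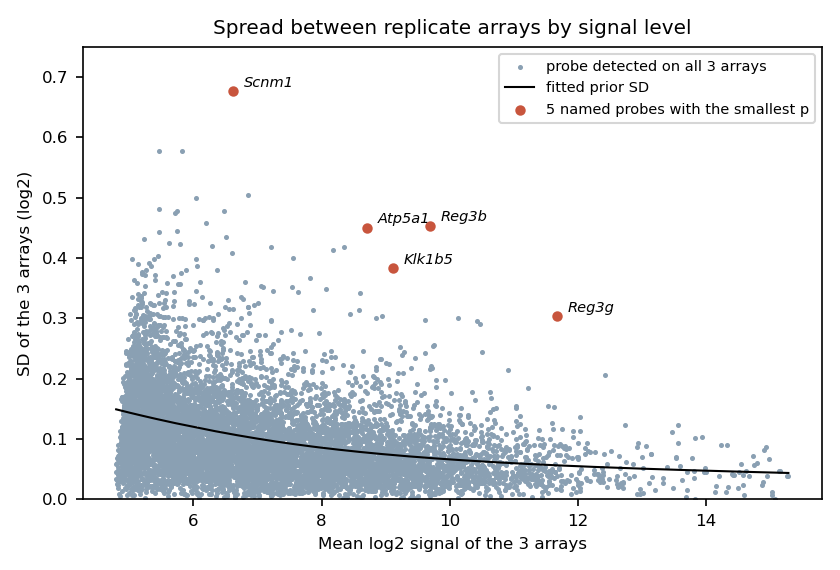
SD of the log2 signal over the 3 arrays (vertical axis) against the mean log2 signal (horizontal axis), 1 point per probe detected on all 3 arrays (8486 probes); the line is the SD expected at each level from the fitted trend and the red points are the 5 named probes with the smallest p in the F test. Most probes lie under 0.191, and Scnm1, at 0.677, has the highest SD.

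The delta cell list's medians differed by 0.0307 log2 units between the highest and the lowest array (13.2nd percentile of random lists of the same size and level), the islet hormones' by 0.0463 (45.8th), the endocrine transcription factors' by 0.0655 (59.2nd) and the myeloid list's by 0.0551 (60.4th). With median scaling, where the median of all detected probes also differed by 0.150 between the arrays, these ranges were 0.197 (62.1st percentile), 0.198 (73.8th), 0.206 (77.9th) and 0.223 (90.02nd). Smaller ranges were found for the delta cell list without replicate 3 (0.00710), the islet hormones without replicate 1 (0.0169) or 3 (0.00259), the endocrine transcription factors without replicate 2 (0.0256) or with all members (0.0252), and the myeloid list without replicate 1 (0.0145) or 2 (0.0299) or with all members (0.0114). None of these 4 lists passed the 95th percentile under any alternative run. The Notch pathway list, with 4 detected genes, was the 1 of 17 lists above the 95th percentile (range 0.20, 96.3rd percentile, highest on replicate 3), where chance alone gives 0.85 lists. Its range was 0.31 with median scaling (95.3rd percentile), 0.149 with all members (98.35th) and 0.183 without replicate 2 (96.6th). Without replicate 1 it was at the 92.6th percentile and without replicate 3 at the 54.7th (range 0.059). The proliferation list was above the 95th percentile without replicate 2 (96.1st), and the beta cell (97.47th) and neuroendocrine secretory lists (95.9th) without replicate 3.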

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

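No paired analysis was possible because the series holds 1 group. The number of detected genes, 6787, stayed within a factor of 1.5 under the 8 alternatives run, from 5872 at a detection p of 0.01 to 7421 with 2 of 3 arrays (6917 to 7159 with a replicate left out). The acinar enzyme and early response lists passed under every alternative run; 3 lists passed as set, 5 at a detection p of 0.01, and 2 without olfactory receptors in the background and without shared members (both chosen after seeing the data), and no list was detected less often than other genes under any. Lists that did not pass changed direction in 8 cases, without passing: the beta cell list without shared members (1 detected gene), the Notch list (4 detected) at a detection p of 0.01, with adjusted detection p and in the one-sample limma test, the mesenchyme list (5) with 2 of 3 arrays and without replicate 2, and the proliferation list (3) at a detection p of 0.01 and with adjusted detection p. The mean r between arrays, 0.9956, was 0.9971 with quantile normalization without background correction, 0.9967 in the authors' processed values and 0.9970 with an offset of 50. The mean over the 3 pairs of the median absolute log2 difference, 0.0991, became 0.0703, 0.0744 and 0.0734 under these, 0.135 with median scaling and 0.0809 over all probes, where the larger offset or the uncorrected background shrinks differences of dim probes by construction. The F test called 0 probes as set, 36 with median scaling and 22 over all probes, 0 under each other alternative, and 0 with a robust prior variance (chosen after seeing the data; limma, smallest adjusted p 0.0717); Reg3b, Scnm1, Atp5a1, Reg3g and Klk1b5 were among both the 36 and the 22. The prior degrees of freedom were 7.93 as set, 28.6 over all probes and infinite with median scaling. Over all probes, the values of each probe were those of the main run. For a probe tested in both, only the fitted prior and the number of tests could change the call. The cause of the change in calls with median scaling was not tested, nor was that of the other changes. Adjusted over the list alone, the 4 genes became 7 over all probes and with the robust prior, 1 without a variance trend (Cd3e), and 2 to 4 with a replicate left out; with median scaling Gapdh and Cd3e did not pass and Iapp and Adgre1 did. The 1 list above the 95th percentile of shift became 2 with unmatched random lists (Notch and proliferation) and 0 to 2 with a replicate left out. Of 107 named levels, those higher by at least 1 SD numbered 85 with quantile normalization alone, 88 (and 3 lower) in the authors' processed values and 84 with an offset of 50, and 0 moved so far with median scaling. Leaving out 1 of 3 arrays cannot move a mean by the SD of those same 3 arrays. The 0 levels that moved with a replicate left out therefore show nothing. Dim signals limit the reading: a probe at background gives only an upper bound on its gene.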

Other observations

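Of the tests in this part, those on the myeloid genes and on the acinar enzymes were chosen after the results were seen. The tests on gut hormones and gene families were set before any gene's values were seen, and that on probe pairs after the spread of the arrays was known but before its own result. The Reg family, secreted proteins of acinar cells that rise in pancreatitis, was detected on all 3 arrays for 5 of the 6 members looked at: Reg2 read 14.88 ± 0.028, Reg3a 15.13 ± 0.046, the brighter probe of Reg3b 14.94 ± 0.087, Reg3d 12.99 ± 0.070 and Reg3g 11.67 ± 0.30 (log2, mean ± SD, n = 3), and Reg4 was above background on 2 arrays (4.88 ± 0.14). These genes were chosen after their values were seen, and no probe sequence was used to tell near-identical members apart. Of the Y-linked genes, looked up after the tests, Eif2s3y (8.47 ± 0.19) and Uty (5.0 ± 0.073) were detected on all 3 arrays and Kdm5d (4.89 ± 0.13) on 2, and Xist, the RNA of the inactive X chromosome, read 4.77 ± 0.050 and passed the detection threshold on 2. Rag1 (4.47 ± 0.097) and Rag2 (4.25 ± 0.019) were at background.

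Among gene families taken by symbol, 37 of 40 measured subunit genes of mitochondrial complex I (92.5%; Fisher's exact test, adjusted p = 4.41e-11), 55 of 71 ribosomal protein genes (77.5%; 1.63e-09) and 27 of 37 proteasome subunit genes (73.0%; 2.33e-04) were detected on all 3 arrays, more often than other genes. Olfactory receptors (19 of 1058; 7.52e-214), Hox genes (2 of 38, 5.26%; 2.69e-06) and keratins (9 of 44, 20.5%; 0.00766) were detected less often. The hypothesis that genes of excitable cells belong to what the sorted cells broadly express was tested on 4 families: 0 were detected more often than other genes, and potassium channels (15 of 80, 18.8%; adjusted p = 6.22e-05) and sodium channels (0 of 8; 0.0309) less often. Voltage-gated calcium channels (5 of 20; 0.196) and synaptotagmins (5 of 17; 0.461) did not pass. The bound set in advance for rejecting this hypothesis, 0 families, was met, but that bound was wrong: an excitable cell uses few members of each family, no sample of such cells was analysed, and a probe at background does not show a silent gene. The hypothesis stays open. The hypothesis of a wider gut-like endocrine program was tested on 12 genes listed as gut hormones, although Tph1 among them encodes an enzyme of serotonin synthesis. Of these, 6 were detected, which did not pass the test (odds ratio 1.45, 95% interval 0.386 to 5.41; Fisher's exact test, p = 0.565). They were Pyy, Ghrl, Gcg and Cck, which the hormone list also holds, and Sct, which encodes secretin (5.82 ± 0.072), and Gip (5.35 ± 0.14). The 6 not detected were Gast, Nts, Tac1, Tph1, Insl5 and Vip. Of the 7 outside the hormone list, 2 were detected (28.6%, against 40.9% of other genes; odds ratio 0.578, 95% interval 0.0550 to 3.53; Fisher's exact test, p = 0.708), so the direction turned without the shared genes. The bound set in advance for rejecting it, a p of 0.05 or more, was met. That bound was too weak to exclude it, since both intervals still hold odds ratios above 1, so the hypothesis stays open.

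Acinar enzyme transcripts in sorted cells meant to have left the acinar state may come from cells that had not converted, from free RNA carried through the sort, or from transcripts that converted cells kept. Carry-over in amounts that differ between sorts would move the enzymes together between the arrays, and their range was at the 15.43rd percentile of random lists. That test is void, since quantile normalization gives the highest ranks the same values on every array: with any replicate left out, the enzymes' range was 0. With median scaling, which fixes no ranks, the enzymes' range was 0.0299 (percentile 0), lowest on replicate 1 and highest on replicate 3. The range of all detected probes' median was 0.150. The enzymes' share of the deposited signal ran the other way, at 8.13%, 7.67% and 7.56% on replicates 1, 2 and 3. Whether differences of probes as bright as these are compressed was not tested, so these values decide nothing and differing carry-over stays open. The acinar transcription factors had a range of 0.0420 (37.2nd percentile; with a replicate left out 0.0105 to 0.0661, at most the 83.0th, without replicate 1) and of 0.142 with median scaling (21.6th), and a constant share of carry-over and retained transcripts cannot be told apart here, because no unsorted or untreated sample was analysed.

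Lyz2 (level 10.13 ± 0.30) and H2-Aa (10.42 ± 0.30) were higher on replicate 3 than on the mean of replicates 1 and 2 by 0.50 and 0.51 log2 units. A candidate explanation of the technical kind is that more myeloid cells passed the Cherry gate in that sort, which would raise the other myeloid genes by about as much. The median difference of the other 6 detected myeloid genes was -0.014 (SE 0.083), from -0.34 for Tyrobp to 0.13 for Adgre1. That of all 8, with Lyz2 and H2-Aa, was 0.031 (SE 0.13, SD of the members 0.29). With median scaling it was 0.14, where the 2 genes rose by 0.61. Both medians of all 8 lay below the rise by more than the members' SD. These values argue against a rise of about 0.50 shared by all 8 genes, as more myeloid cells in constant proportion would give. Lyz2 and H2-Aa were picked from the 8 for their spread, and genes of 1 array are not independent. A smaller increase in myeloid cells therefore stays open. Myeloid cells of another make-up, a change in expression within the cells and a technical difference of that array stay open, and the design, with 1 group, gave no biological explanation to test. Among the 407 probes with an unadjusted p under 0.05 in the F test, the array apart from the others was that of replicate 1 for 181, of replicate 2 for 81 and of replicate 3 for 145, and it was the higher one for 83, 42 and 120 of these. Over all 8486 tested probes, the array apart was that of replicates 1, 2 and 3 for 3184, 2658 and 2644. The 407 are no more than a p under 0.05 gives by chance among so many probes, so no pattern is read from these counts.

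The small spread between the arrays may be mostly measurement noise of single probes, in which case 2 probes of the same gene would deviate independently of each other. Across 1065 genes with 2 detected probes, the deviations correlated at r = 0.0837 (Spearman's rho 0.0972; 95% bootstrap interval over genes 0.0417 to 0.128; 1000 shuffled pairings reached at most 0.0612). The value is above every shuffled pairing, which argues against noise alone, with no part shared by 2 probes of a gene. It is below the bound of 0.1 set in advance for rejection, so noise as the larger part of the spread stays open. Pairs of probes on different transcripts would also lower r and were not tested. Whether the 3 arrays hold RNA of 3 animals, of pools or of 1 preparation cannot be read from this.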
